A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

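Total RNA from 12 cultures of Saccharomyces cerevisiae was measured on Affymetrix arrays after biotin labelling, per the labels, with 3 biological replicates of each of 4 groups: CEN.PK 113-7D and YSBN2, each in aerobic batch and in glucose-limited chemostat. RNA integrity was assessed on a Bioanalyzer before hybridization, per the labels' protocols. R 2.6, the affy package and RMA are named as tools per the submitters' processing notes, which give neither their order nor their settings. Background correction, normalization method and filters are not given in the sources used here. The deposited values were read as log2 signals, because they run from 1.69 to 16.2, the range of log2 of a 16-bit scanner signal. The log base itself is not stated in the labels. Deposited array medians still differed, from 11.02 to 11.37, and the lowest values gathered at a floor near 2. The 10th percentile of an array ran from 4.13 to 7.34. No value was missing, and no deposited column was left unused.

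Every array gave values for the same 5716 probe sets, and the 3 arrays per group limit the precision. Of the probe sets 5498 were paired with 1 gene, 0 with several and 218 with none. All 5498 gene names matched the RefSeq table of assembly R64, with 12 symbols updated to current names, for 5449 genes, 47 of them with several probe sets. Among the probe sets 106 have the suffix s_at and 26 the suffix x_at, which mark sets that may also read near-identical genes. No coordinates were used. Within groups the SD depended on level, with a median of 0.661 for probe sets with means from 4 to 6 and of 0.084 for those at 14 or above. For each probe set with a mean under 2 the arrays were nearly constant (median SD 0.005), so small differences at the floor can pass the test.

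The differences were estimated with limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group over all 12 arrays, 5 contrasts, and eBayes without trend or robust settings (8 residual degrees of freedom, 1.34 prior). The contrasts were chemostat minus batch within each strain, YSBN2 minus CEN.PK 113-7D within each culture, and the difference of the chemostat effect between the strains. Moderated two-sided p-values were adjusted by Benjamini-Hochberg over the 5716 probe sets of a contrast, and probe sets with an adjusted p under 0.05 are named as called. No probe set was filtered out. Errors given with differences are limma's standard errors, and errors given with levels are SDs over 3 arrays. Agreement between effects was described by Pearson's r and Spearman's rho across probe sets without a p-value.

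For gene lists the brightest probe set of each gene over the 12 arrays was used, and lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists tested of 34. A list of 3 measured genes was only described. Camera with an estimated correlation and fry were the alternatives. With the preset correlation 17, 19, 20, 14 and 15 lists were called in the 5 contrasts in the order above. Counts within a list are given over all probe sets and adjusted over the list alone. Genes are named by a rule: the 10 largest rises and 10 largest falls per contrast among called probe sets with 1 gene, and for comparisons of 2 groups with no overlap between the arrays of the groups, and up to 3 called members per direction of each list, with any member open to naming in lists of 15 or fewer. Genes outside that rule are said to be chosen after their values were seen.

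The groups, contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were a common array median, quantile normalization, cyclic loess, leaving out the 25% or 50% dimmest probe sets, 1 probe set per gene, eBayes with trend and robust settings, array weights, the replicate number as a block, an adjusted p under 0.01, treat at 1.5-fold, leaving out each array in turn, and fitting only the 6 arrays compared. Raising values under 6 to 6, the replicate block within 6 arrays, and list medians under a common array median and quantile normalization were chosen after seeing the data. The labels give replicate numbers 1 to 3 but no shared day or batch, so deviations of same-numbered arrays from their group means were correlated. Between CEN.PK 113-7D batch and chemostat arrays r was 0.5, 0.28 and 0.31. Each was over 0.1, with 5 of 6 arrays correlating best with their own number, so they were taken as paired from the data alone. CEN.PK 113-7D batch and YSBN2 chemostat arrays also gave 5 of 6, so that count is not specific. For the other pairs compared the smallest r was -0.17, 0 and -0.1, and no pairing was taken.

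The fit was tested on simulated data. With log2 changes of 0.5, 1, 2 and 3 in 50 probe sets each, 42%, 62%, 92% and 100% were recovered for CEN.PK 113-7D culture. Of the calls 5.7% were false. For the difference of effects the shares were 16%, 40%, 68% and 90%, with 5.3% false. With the proteasome list moved by 0.5, camera called it and 0 other lists of 33. That does not test false list calls among correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.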

Results

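Transcript levels were measured on Affymetrix arrays in 2 strains of Saccharomyces cerevisiae, CEN.PK 113-7D and YSBN2, each grown in aerobic batch culture and in glucose-limited chemostat culture. The labels describe CEN.PK 113-7D as a prototroph of mating type a. YSBN2 is a prototrophic FY strain (S288C lineage) with 2 different disrupted ho alleles (ho::Ble/ho::HphMX4). That genotype is written as for a diploid, but the labels state neither ploidy nor mating type. Each of the 4 groups had 3 biological replicates with 1 array each, 12 arrays in all. Batch cultures started at 30 g/L glucose, and chemostats were fed 7.5 g/L glucose and 0.3 g/L ethanol at a dilution rate of 0.1 per h, all at 30 °C and pH 5 in 4 L reactors. Values were read as log2 signals for 5716 probe sets, and all differences are on that scale. Array medians ran from 11.02 to 11.37, and between 6.4% and 9.8% of the probe sets of an array lay under 4, close to a floor near 2 where the arrays carry no information on level. The number of arrays limits the precision of each value.

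HO, which encodes the endonuclease of mating-type switching and is the disrupted gene of YSBN2, was examined first. Its probe set read 12.62, 12.55 and 12.46 in the 3 CEN.PK 113-7D batch arrays and 11.46, 11.78 and 11.59 in the chemostat arrays. In YSBN2 it read 2.39, 2.39 and 2.30 in batch and 2.38, 2.11 and 2.11 in the chemostat, at the floor in all 6 arrays. Whether the probe set lies inside the disrupted part of HO is not settled here. Replicates correlated across probe sets at 0.961 or above. The third YSBN2 batch array stood apart, with 196 probe sets at least 2 log2 units from the mean of the other two (178 higher, 18 lower), against 2 to 77 in the other arrays. HXT2, a glucose transporter gene chosen after its values were seen, read 4.26, 4.21 and 14.04 in the YSBN2 batch arrays, and NRG1, a glucose-responsive repressor gene chosen the same way, read 8.09, 8.79 and 5.26.

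How did the chemostat change the transcripts of CEN.PK 113-7D relative to batch? Among the largest rises were genes for the use of carbon sources other than glucose. RGI2, a gene of respiratory growth, lay at 2.02 ± 0.02 in batch and 15.49 ± 0.11 in the chemostat (mean ± SD, n = 3 arrays each), a rise of 13.47 ± 0.06 (SE, adjusted p = 8.6e-15). The acetate permease gene ADY2 rose by 12.36 ± 0.09, the lactate and pyruvate permease gene JEN1 by 12.02 ± 0.11 and the glucose-repressed alcohol dehydrogenase gene ADH2 by 12.00 ± 0.86. HXT1, encoding a low-affinity glucose transporter, went the other way, from 13.08 ± 0.23 to 2.97 ± 0.31 (difference -10.11 ± 0.35, adjusted p = 1.3e-08), and the low-affinity iron transporter gene FET4 fell by 8.75 ± 0.63.

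Among the 10 largest rises were also FDH1 (formate dehydrogenase, 12.76 ± 0.13), SPG4 (12.38 ± 0.37), SFC1 (mitochondrial succinate-fumarate carrier, 12.34 ± 0.11), CTA1 (peroxisomal catalase, 12.20 ± 0.47), GRE1 (a stress hydrophilin, 12.12 ± 0.25) and HXT5 (a hexose transporter, 11.94 ± 0.08). Each of the 10 lay at 4.07 or below in batch, close to the floor, so the size of the rise depends on that floor. The 10 largest falls included the oligopeptide transporter genes OPT1 (-6.95 ± 0.64) and OPT2 (-6.67 ± 0.20), HMS2 (-7.20 ± 0.55) and the glucose repressor gene MIG2 (-5.38 ± 0.99, adjusted p = 0.0012). With values under 6 raised to 6, a setting chosen after seeing the data, the MIG2 difference was -1.76 and was not called (adjusted p = 0.18), and that of YOL014W went from -5.20 ± 0.59 to -1.31 (adjusted p = 0.087).

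Several carbon and energy lists rose, while ethanol formation fell and glycolysis (5 higher, 6 lower, median -0.07, adjusted p = 0.48) was not called. Of 18 genes for ethanol and acetate use, the glyoxylate cycle and gluconeogenesis, 17 were called higher, 0 lower and 1 not (same over the list alone), with ADY2, SFC1 and JEN1 in front. The gluconeogenesis median was 8.11 (adjusted p = 2.3e-10, or 0.082 with estimated correlation). Among 20 genes of fatty acid oxidation and the peroxisome, 20 were called higher, 0 lower and 0 not (same over the list alone), CTA1 and the acyl-CoA oxidase gene POX1 (11.50 ± 0.12) among them. The fatty acid median was 5.63 (adjusted p = 2.4e-10, or 0.082 with estimated correlation). For the respiratory chain and ATP synthase 30 were called higher, 0 lower and 3 not (31 and 0 over the list alone), including the NADH dehydrogenase gene NDE2 (10.68 ± 0.35) and the ATP synthase gene ATP14 (1.18 ± 0.15). The respiratory median was 0.75 (adjusted p = 4.8e-08, or 0.097 with estimated correlation). In the TCA cycle 14 were called higher, 1 lower and 1 not (same over the list alone), with SDH2 of succinate dehydrogenase at 2.27 ± 0.19 and IDH2 of isocitrate dehydrogenase at -0.31 ± 0.09. The TCA cycle median was 1.48 (adjusted p = 1.6e-05, or 0.26 with estimated correlation). The IDH2 call was lost without the second or the third batch array or the first or second chemostat array (adjusted p from 0.05 to 0.055), and with cyclic loess (adjusted p = 0.076). Of the genes of trehalose and glycogen, the storage carbohydrates, 18 were called higher, 0 lower and 1 not (19 and 0 over the list alone), with the glycogen phosphorylase gene GPH1 at 10.69 ± 0.15 and GAC1 at 8.91 ± 1.07. The storage carbohydrate median was 4.06 (adjusted p = 3.7e-08, or 0.17 with estimated correlation). Heat shock and general stress genes rose too: 19 were called higher, 1 lower and 2 not (same over the list alone), with DDR2 at 11.07 ± 0.66. The stress median was 3.73 (adjusted p = 1.4e-07, or 0.14 with estimated correlation). For vacuolar proteases and autophagy 23 were called higher, 0 lower and 3 not (24 and 0 over the list alone), with ATG14 at 4.02 ± 0.74. The vacuolar median was 1.81 (adjusted p = 3.1e-07, or 0.14 with estimated correlation).

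Of the genes for sucrose, galactose and maltose use 6 were called higher, 0 lower and 6 not (same over the list alone), with the galactose signalling gene GAL3 at 6.02 ± 0.32 and the maltose transporter gene MAL31 at 6.26 ± 0.83. The sugar list median was 1.85 (adjusted p = 0.022, or 0.14 with estimated correlation). Among thiamine and pyridoxine genes 14 were called higher, 1 lower and 2 not (same over the list alone), with the transporter genes THI73 at 3.22 ± 0.57 and THI72 at 3.12 ± 0.57, or 0.76 and not called (adjusted p = 0.082) with values under 6 raised to 6. The thiamine list median was 1.20 (adjusted p = 0.0021, or 0.31 with estimated correlation). Genes activated by the heme-responsive factor Hap1 were higher: 10 were called higher, 1 lower and 6 not (11 and 1 over the list alone), with MCR1 at 1.90 ± 0.15. The Hap1 list median was 0.64 (adjusted p = 0.0092, or 0.15 with estimated correlation). This list shares 6 of its 17 measured genes with the ergosterol list and 4 with the respiratory list. In ergosterol biosynthesis 16 were called higher, 4 lower and 6 not (same over the list alone), with ERG5 at 1.08 ± 0.10 and the sterol regulator gene ECM22 at 1.51 ± 0.18. The ergosterol median was 0.39 (adjusted p = 0.032, or 0.44 with estimated correlation). That call was lost without the first batch array (adjusted p = 0.054), the first chemostat array (adjusted p = 0.052) or the second (adjusted p = 0.05), and with a common array median the counts were 9 higher and 6 lower.

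Lists of cytosolic protein synthesis were lower in the chemostat, while mitochondrial ribosomal proteins (9 higher, 8 lower of 69, median 0.02, adjusted p = 0.45) were not called. Of the cytosolic ribosomal protein genes 0 were called higher, 98 lower and 30 not (0 and 101 over the list alone). The ribosomal protein median was -0.30 (adjusted p = 8.2e-18, or 0.14 with estimated correlation). That list holds RPP1, a subunit of RNase P and no ribosomal protein, which fell by 2.45 ± 0.66. With cyclic loess, 57 of the ribosomal protein genes were lower. In ribosome biogenesis 0 were called higher, 28 lower and 14 not (same over the list alone), with the RNA polymerase I gene RPA43 at -1.59 ± 0.23 and the fibrillarin gene NOP1 at -1.45 ± 0.18. The ribosome biogenesis median was -0.87 (adjusted p = 6.4e-09, or 0.4 with estimated correlation). For translation factors 1 were called higher, 30 lower and 6 not (same over the list alone), with the elongation factor gene TEF4 at -1.75 ± 0.07. The translation factor median was -0.54 (adjusted p = 3.8e-08, or 0.14 with estimated correlation). Amino acid biosynthesis fell, where 7 were called higher, 39 lower and 12 not (7 and 40 over the list alone), with the threonine pathway gene THR1 at -2.18 ± 0.37 and the leucine pathway gene LEU9 at -2.05 ± 0.09. The amino acid median was -0.48 (adjusted p = 3.8e-08, or 0.14 with estimated correlation). Among sulfur amino acid genes 4 were called higher, 14 lower and 8 not (same over the list alone), with MET8 at -4.74 ± 0.57 and the S-methylmethionine permease gene MMP1 at 1.62 ± 0.18. The sulfur list median was -0.42 (adjusted p = 0.0021, or 0.13 with estimated correlation). For ethanol formation 1 were called higher, 5 lower and 1 not (same over the list alone), with the alcohol dehydrogenase gene ADH1 at -0.52 ± 0.07. The ethanol formation median was -0.42 (adjusted p = 0.033, or 0.14 with estimated correlation), a call lost with cyclic loess (adjusted p = 0.12) or without the 25% dimmest probe sets (adjusted p = 0.061). The proteasome list (12 higher and 0 lower of 34, median 0.21, adjusted p = 0.06) was not called, but was with the replicate number as a block (adjusted p = 0.049), cyclic loess (adjusted p = 0.0036), values under 6 raised to 6 (adjusted p = 0.029) or without the 25% dimmest probe sets (adjusted p = 0.044), and its median turned to -0.08 with a common array median.

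In this comparison 3207 of 5716 probe sets were called by limma at an adjusted p under 0.05, 1936 higher and 1271 lower, of which 1107 and 445 changed at least 2-fold. In 3913 probe sets (68.5%, against 10% by chance) the 3 arrays of one culture lay wholly above the 3 of the other. Setting all arrays to a common median shifted the median difference of all probe sets by -0.28 and quantile normalization by -0.24, so that 40.4% and 37.8% of the calls were higher against 60.4% as deposited. Rises smaller than that shift therefore have no settled direction.

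**Figure D1:**
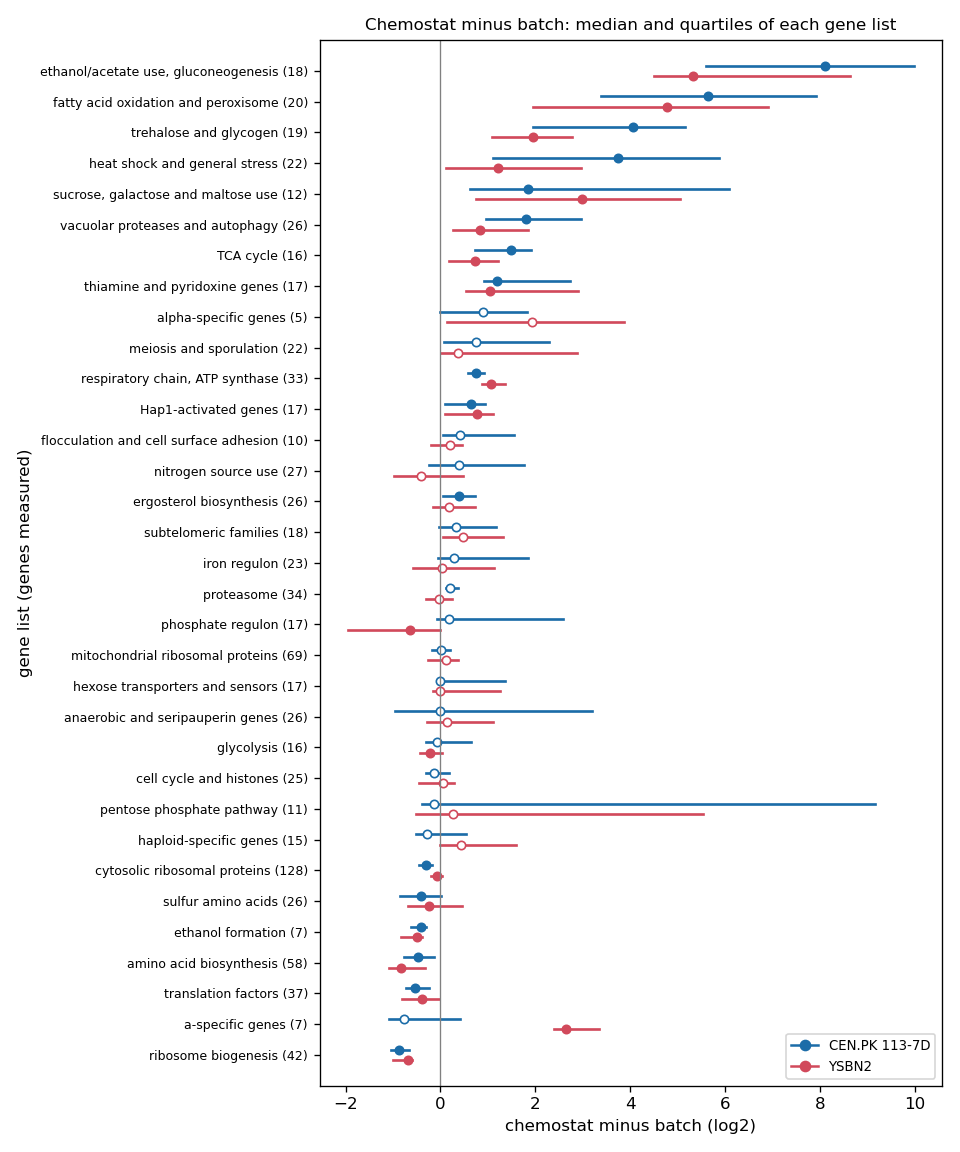
Log2 difference between chemostat and batch for each gene list in CEN.PK 113-7D and in YSBN2. Points are the list medians, lines the quartiles over the genes measured (numbers in parentheses), and filled points the lists called with the preset correlation. The phosphate list lies at a median of 0.19 in CEN.PK 113-7D and -0.64 in YSBN2.

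The same question was asked of YSBN2. RGI2 rose from 2.02 ± 0.01 to 15.71 ± 0.03 (n = 3 arrays each), by 13.70 ± 0.06 (SE, adjusted p = 7.4e-15), followed by ADY2 (13.01 ± 0.09), JEN1 (12.08 ± 0.11), SFC1 (11.70 ± 0.11) and ADH2 (11.58 ± 0.86). PHO84, encoding the high-affinity phosphate transporter, fell from 14.62 ± 0.26 in batch to 2.35 ± 0.47 in the chemostat (difference -12.27 ± 0.35, adjusted p = 5e-09, or -8.62 with values under 6 raised to 6), and SPL2, a regulator of low-affinity phosphate transport, fell by 9.54 ± 0.55. The amino acid permease genes DIP5 and GNP1 fell by 8.84 ± 0.53 and 7.52 ± 0.35. HXT1 fell by 11.07 ± 0.35, OPT2 by 11.40 ± 0.20 and IMD2, an IMP dehydrogenase gene whose probe set may also read close relatives, by 9.68 ± 0.19. Wherever one group lies near the floor, as for RGI2 and PHO84 here, the size of the difference depends on that floor, in every comparison.

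Respiratory chain and ATP synthase genes rose in YSBN2: 32 were called higher, 0 lower and 1 not (same over the list alone), with NDE2 at 9.75 ± 0.35, the Rieske protein gene RIP1 at 1.80 ± 0.18 and ATP14 at 1.73 ± 0.15. The respiratory median was 1.07 (adjusted p = 1.6e-11, or 0.057 with estimated correlation). Of the genes for ethanol and acetate use, the glyoxylate cycle and gluconeogenesis 15 were called higher, 0 lower and 3 not (same over the list alone). The gluconeogenesis median was 5.31 (adjusted p = 2.6e-10, or 0.057 with estimated correlation). For fatty acid oxidation and the peroxisome 18 were called higher, 0 lower and 2 not (19 and 0 over the list alone), with POX1 at 11.03 ± 0.12 and CTA1 at 10.40 ± 0.47. The fatty acid median was 4.78 (adjusted p = 4e-10, or 0.06 with estimated correlation). Among trehalose and glycogen genes 16 were called higher, 0 lower and 3 not (same over the list alone), with GAC1 at 7.59 ± 1.07 and GPH1 at 3.28 ± 0.15. The storage carbohydrate median was 1.96 (adjusted p = 4.1e-05, or 0.38 with estimated correlation). In the TCA cycle 11 were called higher, 2 lower and 3 not (12 and 2 over the list alone), with SDH2 at 2.63 ± 0.19 and SDH3 at 1.73 ± 0.10. The TCA cycle median was 0.73 (adjusted p = 0.0016, or 0.45 with estimated correlation). For heat shock and general stress 13 were called higher, 1 lower and 8 not (same over the list alone), with DDR2 at 10.36 ± 0.66 and SPI1 at 5.29 ± 0.41. The stress median was 1.21 (adjusted p = 0.003, or 0.38 with estimated correlation). Vacuolar protease and autophagy genes were mostly higher: 18 were called higher, 3 lower and 5 not (same over the list alone), with ATG9 at 2.52 ± 0.31 and ATG18 at -1.60 ± 0.44. The vacuolar median was 0.84 (adjusted p = 0.0064, or 0.45 with estimated correlation).

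Thiamine and pyridoxine genes rose, where 12 were called higher, 1 lower and 4 not (same over the list alone), with THI73 at 4.21 ± 0.57. The thiamine list median was 1.05 (adjusted p = 0.003, or 0.38 with estimated correlation), a call lost without the 25% dimmest probe sets (adjusted p = 0.078). For sucrose, galactose and maltose use 9 were called higher, 0 lower and 3 not (9 and 1 over the list alone), with GAL3 at 6.95 ± 0.32. The sugar list median was 2.98 (adjusted p = 0.011, or 0.15 with estimated correlation). Of the genes activated by Hap1 11 were called higher, 3 lower and 3 not (12 and 3 over the list alone), with ERG3 at 1.17 ± 0.08. The Hap1 list median was 0.77 (adjusted p = 0.026, or 0.35 with estimated correlation), a call lost without the first batch array (adjusted p = 0.054). The a-specific genes, transcribed in cells of mating type a, were higher in the chemostat: 6 were called higher, 0 lower and 1 not (same over the list alone), with the a-agglutinin gene AGA2 at 5.71 ± 0.40, the a-factor gene MFA2 at 3.93 ± 0.87 and the alpha-factor receptor gene STE2 at 2.19 ± 0.63. The a-specific median was 2.65 (adjusted p = 0.012, or 0.38 with estimated correlation). The STE2 call was lost without the second chemostat array (adjusted p = 0.057), in a fit of the 6 arrays (adjusted p = 0.091) and with the replicate number as a block in that fit (adjusted p = 0.14), where the MFA2 call was lost too (adjusted p = 0.096). In the third YSBN2 batch array the median of these 7 genes stood 1.16 above the other two.

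Amino acid biosynthesis fell in YSBN2: 3 were called higher, 45 lower and 10 not (same over the list alone), with THR1 at -2.76 ± 0.37 and the branched-chain pathway gene ILV6 at -2.48 ± 0.22. The amino acid median was -0.83 (adjusted p = 1.9e-12, or 0.096 with estimated correlation). In ribosome biogenesis 0 were called higher, 25 lower and 17 not (0 and 26 over the list alone), with RPA43 at -1.59 ± 0.23. The ribosome biogenesis median was -0.69 (adjusted p = 8.8e-07, or 0.52 with estimated correlation). The third batch array read that list 0.98 above the other two, and without it the median was -0.45 (adjusted p = 3.4e-06). For translation factors 2 were called higher, 20 lower and 15 not (same over the list alone), with TEF4 at -1.55 ± 0.07. The translation factor median was -0.38 (adjusted p = 4e-05, or 0.31 with estimated correlation). Of the cytosolic ribosomal protein genes 1 were called higher, 31 lower and 96 not (1 and 26 over the list alone), with RPS11A at -0.97 ± 0.13. The ribosomal protein median was -0.08 (adjusted p = 0.0016, or 0.52 with estimated correlation). Without the first batch array or the third chemostat array the median of that list was -0.05 (adjusted p = 0.0035 and 0.0069), with a common array median 52 were lower, and with cyclic loess the median was 0.00 and the call was lost (adjusted p = 0.56). Of the phosphate regulon 3 were called higher, 10 lower and 4 not (same over the list alone), with PHM6 at -3.98 ± 0.43 and PHM7, encoding a membrane protein, at 7.21 ± 0.41. The phosphate median was -0.64 (adjusted p = 0.011, or 0.45 with estimated correlation).

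Sulfur amino acid genes were mostly lower: 5 were called higher, 14 lower and 7 not (same over the list alone), with MET8 at -4.10 ± 0.57. The sulfur list median was -0.24 (adjusted p = 0.015, or 0.19 with estimated correlation), a call lost with cyclic loess (adjusted p = 0.09) or without the 25% dimmest probe sets (adjusted p = 0.072). For ethanol formation 0 were called higher, 5 lower and 2 not (0 and 6 over the list alone), with ADH1 at -0.77 ± 0.07. The ethanol formation median was -0.49 (adjusted p = 0.0065, or 0.096 with estimated correlation). In glycolysis 2 were called higher, 9 lower and 5 not (same over the list alone), with the enolase gene ENO2 at -0.75 ± 0.08 and the phosphofructokinase gene PFK2 at -0.72 ± 0.07. The glycolysis median was -0.21 (adjusted p = 0.021, or 0.52 with estimated correlation). The glycolysis call was lost with cyclic loess (adjusted p = 0.24), without the 25% dimmest probe sets (adjusted p = 0.072) and without the second chemostat array (adjusted p = 0.067).

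For YSBN2 limma called 3004 probe sets, 1750 higher and 1254 lower, with 940 and 520 of them changed at least 2-fold, and 3116 without the third batch array. Groups were fully separated in 3359 probe sets (58.8%, against 10% by chance). A common array median shifted the median difference of all probe sets by -0.13 and quantile normalization by -0.11, with 48.5% and 44.7% of the calls higher against 58.3% as deposited.

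Most probe sets called for the culture in both strains went the same way. Across the 5716 probe sets the culture effects of the strains correlated at r = 0.84 (rho = 0.81), where probe sets are not independent replicates and no arrays are shared. Of 2313 probe sets called in both strains, 2254 (97.4%) had the same direction, 1399 higher and 855 lower, against 593 and 279 for independent lists of these sizes.

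How did the strains differ in batch? The a-specific and haploid-specific lists were far lower in YSBN2. HO was at 12.54 ± 0.08 in CEN.PK 113-7D and 2.36 ± 0.05 in YSBN2 (n = 3 arrays each), a difference of -10.18 ± 0.10 (adjusted p = 6.2e-12), followed by BAR1 (the protease that degrades alpha factor, -9.33 ± 0.47), FAR1 (pheromone arrest, -9.22 ± 0.70), the MAP kinase gene FUS3 (-8.52 ± 0.24), MFA2 (-8.27 ± 0.87) and AGA2 (-8.00 ± 0.40). PHO84 was higher in YSBN2, at 14.62 ± 0.26 against 2.39 ± 0.48 (difference 12.23 ± 0.35, adjusted p = 1.3e-08), as were SPL2 (9.63 ± 0.55), the multidrug transporter gene QDR2 (11.42 ± 0.34) and DAL80, a repressor of nitrogen catabolism (9.47 ± 0.35). The glycogen phosphorylase gene GPH1 was higher by 8.31 ± 0.15.

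The remaining large rises were ENA5 (9.41 ± 0.12), a sodium pump gene whose probe set also reads its near-identical neighbours, COS8 of a subtelomeric family with close relatives (9.12 ± 0.09), RSB1 (9.08 ± 0.65), HAL5 (8.81 ± 0.25) and AIF1 (8.78 ± 0.14). All 5 read under 4 in both CEN.PK 113-7D groups. STE2 fell by 7.59 ± 0.63, the a-factor exporter gene STE6 by 7.45 ± 0.36, YER053C-A by 7.79 ± 0.87 and the maltose activator gene MAL33 by 6.85 ± 1.04. The MAL33 call was lost with the replicate number as a block in a fit of the 6 batch arrays (adjusted p = 0.075), a setting chosen after seeing the data.

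**Figure D2:**
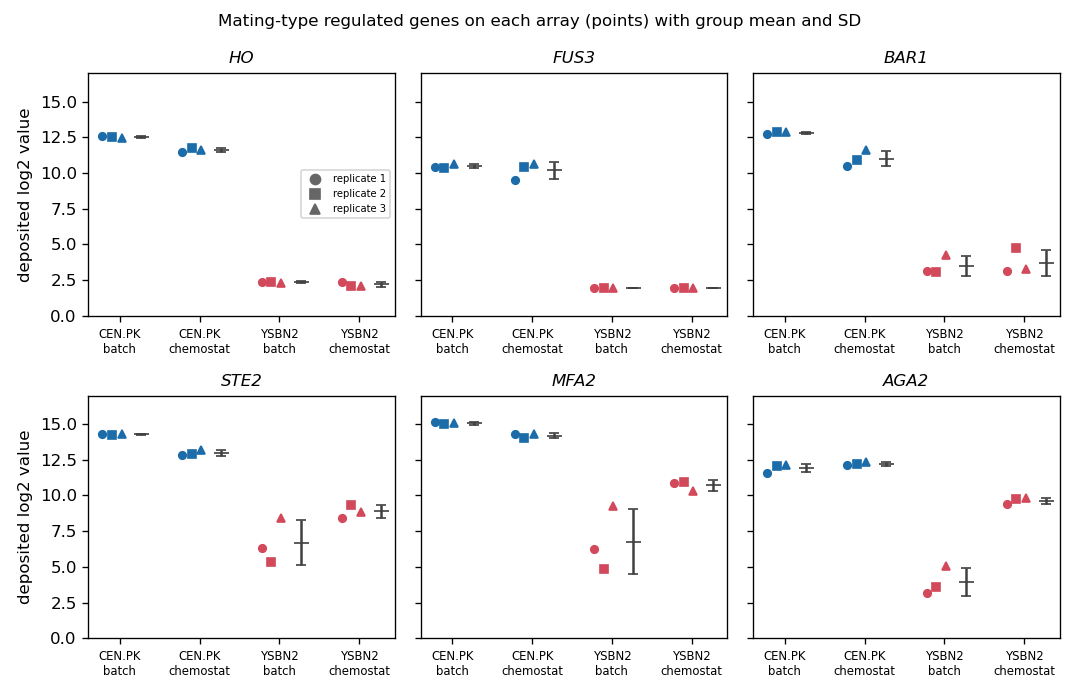
Log2 signal of 6 mating genes in each array (points, marker by replicate) of the 4 groups, with the group mean and SD (bars). HO and FUS3 stayed near the floor in all YSBN2 arrays, while AGA2 lay at 3.92 in YSBN2 batch and 9.63 in the chemostat.

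Haploid-specific genes, which are repressed in a/alpha diploids, were lower in YSBN2: 0 were called higher, 13 lower and 2 not (same over the list alone), with the G protein genes GPA1 at -5.67 ± 0.85 and STE18 at -5.02 ± 0.32 and NEJ1 at -4.38 ± 0.70. The haploid-specific median was -4.38 (adjusted p = 8.4e-14, or 0.05 with estimated correlation). Of the a-specific genes 0 were called higher, 7 lower and 0 not (same over the list alone). The a-specific median was -7.59 (adjusted p = 1.8e-09, or 0.05 with estimated correlation). The third YSBN2 batch array read that list 1.16 above the other two. Mitochondrial ribosomal protein genes were lower: 1 were called higher, 38 lower and 30 not (1 and 49 over the list alone), with RSM25 at -1.54 ± 0.40 and MRPL28 at -1.01 ± 0.28. The mitochondrial ribosomal median was -0.52 (adjusted p = 7.5e-13, or 0.19 with estimated correlation), in a list that the third YSBN2 batch array read 0.43 above the others. Its 1 higher member, MRP8 (0.78 ± 0.12), is not known as a ribosomal protein. Calls were lost for RSM25 without the second or the third CEN.PK 113-7D or the first YSBN2 array (adjusted p from 0.054 to 0.061), and for MRPL28 without the second or the third CEN.PK 113-7D or the first or second YSBN2 array (adjusted p from 0.073 to 0.089). In a fit of the 6 batch arrays both calls were lost as well (adjusted p = 0.098 and 0.094), and with the replicate number as a block in it those of RSM25 (adjusted p = 0.12), MRPL28 (0.08), GPA1 (0.069), NEJ1 (0.054) and RIP1 of the respiratory list (0.056). For the respiratory chain and ATP synthase 1 were called higher, 19 lower and 13 not (2 and 20 over the list alone), with RIP1 at -1.39 ± 0.18, CYT1 at -1.32 ± 0.11 and QCR8 at 2.53 ± 0.25. The respiratory median was -0.47 (adjusted p = 3.8e-08, or 0.05 with estimated correlation). Among genes activated by Hap1 2 were called higher, 11 lower and 4 not (3 and 12 over the list alone), with the cytochrome c gene CYC1 at -2.05 ± 0.11 and HMG1 of sterol synthesis at -1.71 ± 0.06. The Hap1 list median was -0.53 (adjusted p = 2.1e-06, or 0.05 with estimated correlation). In ergosterol biosynthesis 3 were called higher, 15 lower and 8 not (4 and 16 over the list alone), with MVD1 at -1.17 ± 0.11. The ergosterol median was -0.32 (adjusted p = 2.8e-06, or 0.13 with estimated correlation). Proteasome genes were lower by small amounts: 0 were called higher, 17 lower and 17 not (0 and 21 over the list alone), with PRE4 at -0.77 ± 0.10. The proteasome median was -0.31 (adjusted p = 2.7e-07, or 0.16 with estimated correlation). For sulfur amino acids 1 were called higher, 11 lower and 14 not (same over the list alone), with MET8 at -3.53 ± 0.57 and SAM3 at -1.36 ± 0.11. The sulfur list median was -0.33 (adjusted p = 0.00019, or 0.05 with estimated correlation).

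Storage, nitrogen, phosphate and vacuolar genes were higher in YSBN2 batch. For trehalose and glycogen 16 were called higher, 1 lower and 2 not (same over the list alone), led by GPH1. The storage carbohydrate median was 2.10 (adjusted p = 6.3e-10, or 0.13 with estimated correlation), while the difference of the third YSBN2 batch array from the other two was -0.51 for this list. Of the nitrogen source genes 18 were called higher, 3 lower and 6 not (same over the list alone), with DAL80 in front and the amino acid permease gene AGP1 at -1.92 ± 0.27. The nitrogen list median was 1.03 (adjusted p = 6.3e-09, or 0.05 with estimated correlation). In the vacuolar list 19 were called higher, 1 lower and 6 not (same over the list alone), with the mannosidase gene AMS1 at 4.94 ± 0.36. The vacuolar median was 0.98 (adjusted p = 2.4e-07, or 0.13 with estimated correlation). Of the phosphate regulon 12 were called higher, 0 lower and 5 not (12 and 1 over the list alone). PHO84, SPL2 and the acid phosphatase gene PHO5 (7.22 ± 0.20) were in front. PHO5 and DAL80 lay under 4 in both CEN.PK 113-7D groups. The phosphate median was 0.88 (adjusted p = 7.4e-07, or 0.13 with estimated correlation). For heat shock and general stress 11 were called higher, 0 lower and 11 not (same over the list alone). The stress median was 0.64 (adjusted p = 0.00011, or 0.19 with estimated correlation), with a median of 0.42 without the first CEN.PK 113-7D batch array (adjusted p = 0.00029). Cell cycle and histone genes were mostly higher: 14 were called higher, 0 lower and 11 not (15 and 2 over the list alone), with the cyclin gene CLB1 at 1.40 ± 0.07. The cell cycle median was 0.28 (adjusted p = 0.0017, or 0.05 with estimated correlation), and with a common array median 7 were higher and 3 lower. In the TCA cycle 9 were called higher, 1 lower and 6 not (same over the list alone). The TCA cycle median was 0.33 (adjusted p = 0.0097, or 0.51 with estimated correlation), with a median of 0.2 without the first CEN.PK 113-7D array (adjusted p = 0.037) and the call lost without the third YSBN2 array (adjusted p = 0.057). For glycolysis 5 were called higher, 0 lower and 11 not (same over the list alone). The glycolysis median was 0.06 (adjusted p = 0.011, or 0.51 with estimated correlation), a median that a common array median turned to -0.04 while the mean was 0.87.

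The lists of protein synthesis lay slightly lower in YSBN2 batch. Of the cytosolic ribosomal protein genes 0 were called higher, 10 lower and 118 not (0 and 4 over the list alone). The ribosomal protein median was -0.09 (adjusted p = 1.7e-07, or 0.3 with estimated correlation), with 17 lower when arrays had a common median. Among translation factors 1 were called higher, 6 lower and 30 not (1 and 3 over the list alone). The translation factor median was -0.15 (adjusted p = 0.00082, or 0.3 with estimated correlation), where leaving out the second YSBN2 array gave a median of -0.09 (adjusted p = 0.0034) and leaving out the third gave 18 lower. In ribosome biogenesis 0 were called higher, 2 lower and 40 not (0 and 0 over the list alone). The ribosome biogenesis median was -0.25 (adjusted p = 0.0027, or 0.62 with estimated correlation). Without the third YSBN2 array 28 of these genes were lower, with a median of -0.63 (adjusted p = 1.6e-09), without the first the median was -0.16 (adjusted p = 0.023), and without the second it was -0.03 and not called (adjusted p = 0.13). For thiamine and pyridoxine genes 1 were called higher, 6 lower and 10 not (2 and 6 over the list alone), with SNO3 at -3.01 ± 0.30. The thiamine list median was -0.08 (adjusted p = 0.017, or 0.46 with estimated correlation). The direction of that median depended on single arrays: it was 0.04 without the first CEN.PK 113-7D array, 0.02 without the second YSBN2 array, -0.16 without the third CEN.PK 113-7D array, and -0.38 and not called without the third YSBN2 array (adjusted p = 0.054).

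In batch 1661 probe sets were called between the strains, 1060 higher in YSBN2 and 601 lower, with 452 and 162 of them at least 2-fold. Without the third YSBN2 array 2485 were called, 1370 higher and 1115 lower, and without the second 399 were lower. The groups were fully separated in 2292 probe sets (40.1%, against 10% by chance). With a common array median 50% of the calls were higher and with quantile normalization 47.6%, against 63.8% as deposited.

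**Figure D3:**
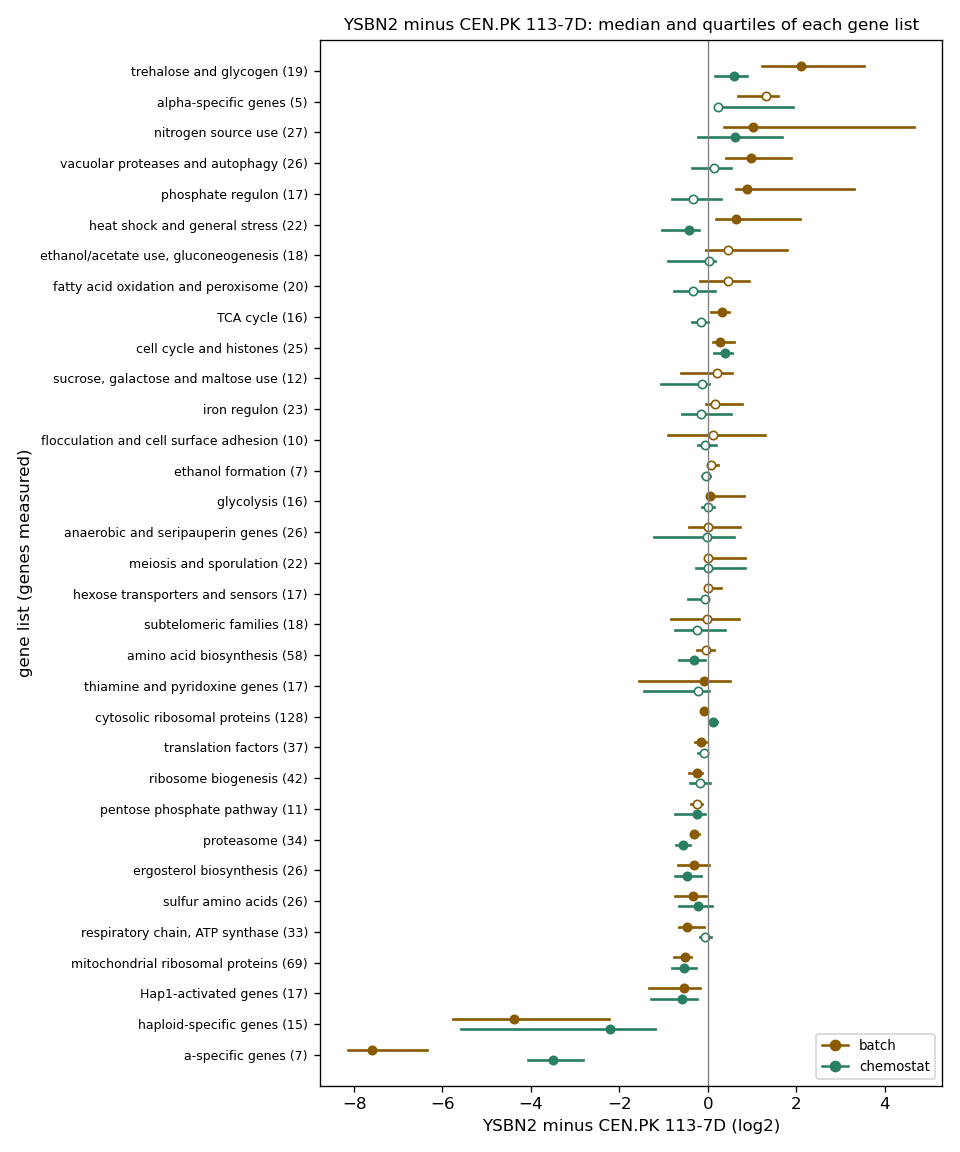
Log2 difference between YSBN2 and CEN.PK 113-7D for each gene list in batch and in the chemostat. Points are list medians, lines the quartiles over the genes measured (numbers in parentheses), and filled points the lists called with the preset correlation. The a-specific list lies at -7.59 in batch and -3.50 in the chemostat.

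In the chemostat the same question was asked of the strains. HO (-9.41 ± 0.10, adjusted p = 1.1e-11), FUS3 (-8.23 ± 0.24) and BAR1 (-7.31 ± 0.47) were again lower in YSBN2, with FUS3 at 1.95 ± 0.00 against 10.19 ± 0.60 (n = 3 arrays each). The seripauperin gene PAU3 (-8.16 ± 0.29, a probe set that reads near-identical PAU genes), the permease gene GNP1 (-7.66 ± 0.35) and the phenylpyruvate decarboxylase gene ARO10 (-6.54 ± 0.68) were lower as well. Higher in YSBN2 were COS8 (9.97 ± 0.09, adjusted p = 5.4e-12), ENA5 (9.87 ± 0.12), HAL5 (9.24 ± 0.25), the siderophore transporter gene ARN2 (7.50 ± 0.15), PHO5 (7.22 ± 0.20) and the mRNA methyltransferase gene IME4 (7.01 ± 0.41). SEO1 (9.36 ± 0.50) and PAU18 (6.63 ± 0.50), both of families with near-identical members, were higher too.

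Proteasome genes were lower in YSBN2: 0 were called higher, 30 lower and 4 not (0 and 32 over the list alone), with RPN10 at -1.54 ± 0.26 and PRE8 at -1.14 ± 0.18. The proteasome median was -0.56 (adjusted p = 3.4e-14, or 0.089 with estimated correlation). Among mitochondrial ribosomal protein genes 0 were called higher, 37 lower and 32 not (0 and 39 over the list alone), with RSM7 at -1.63 ± 0.25 and IMG1 at -1.64 ± 0.38. The mitochondrial ribosomal median was -0.53 (adjusted p = 3.2e-10, or 0.31 with estimated correlation). For haploid-specific genes 0 were called higher, 11 lower and 4 not (same over the list alone), with STE18 at -5.69 ± 0.32 and NEJ1 at -5.67 ± 0.70. The haploid-specific median was -2.22 (adjusted p = 1.8e-09, or 0.077 with estimated correlation). Of the a-specific genes 0 were called higher, 7 lower and 0 not (same over the list alone). The a-specific median was -3.50 (adjusted p = 7.8e-06, or 0.12 with estimated correlation). Genes activated by Hap1 were lower and stayed called with an estimated correlation: 0 were called higher, 13 lower and 4 not (same over the list alone), with CYC1 at -2.18 ± 0.11. The Hap1 list median was -0.58 (adjusted p = 4.1e-08, or 0.031 with estimated correlation). In ergosterol biosynthesis 2 were called higher, 18 lower and 6 not (same over the list alone), with HMG1 at -1.54 ± 0.06 and ERG13 at -1.37 ± 0.10. The ergosterol median was -0.47 (adjusted p = 3.4e-07, or 0.12 with estimated correlation). For amino acid biosynthesis 2 were called higher, 24 lower and 32 not (3 and 25 over the list alone), with TRP4 at -0.99 ± 0.15. The amino acid median was -0.30 (adjusted p = 7.4e-06, or 0.28 with estimated correlation).

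Heat shock and general stress genes, higher in YSBN2 in batch, were lower in the chemostat: 1 were called higher, 11 lower and 10 not (1 and 12 over the list alone). The stress median was -0.43 (adjusted p = 0.00044, or 0.31 with estimated correlation), with 7 lower when arrays had a common median. For sulfur amino acids 2 were called higher, 12 lower and 12 not (2 and 13 over the list alone), with MET8 at -2.89 ± 0.57, or -0.29 and not called (adjusted p = 0.56) with values under 6 raised to 6. The sulfur list median was -0.23 (adjusted p = 0.015, or 0.17 with estimated correlation). In the pentose phosphate pathway 0 were called higher, 5 lower and 6 not (0 and 6 over the list alone), with GND2 at -0.88 ± 0.19 and RPE1 at -0.87 ± 0.19. The pentose phosphate median was -0.25 (adjusted p = 0.025, or 0.39 with estimated correlation), a call lost without the 25% dimmest probe sets (adjusted p = 0.19) or the second YSBN2 array (adjusted p = 0.11). Higher were cell cycle and histone genes, where 16 were called higher, 1 lower and 8 not (same over the list alone), with the chitinase gene CTS1 at 0.95 ± 0.08, a call that stayed with an estimated correlation. The cell cycle median was 0.40 (adjusted p = 1.2e-05, or 0.031 with estimated correlation). Cytosolic ribosomal protein genes lay slightly higher: 29 were called higher, 1 lower and 98 not (24 and 0 over the list alone). The ribosomal protein median was 0.13 (adjusted p = 7.8e-06, or 0.49 with estimated correlation), with 18 higher when arrays had a common median and 19 with cyclic loess. Of the nitrogen source genes 12 were called higher, 3 lower and 12 not (13 and 4 over the list alone), with DAL80 at 5.28 ± 0.35 and the allantoin permease gene DAL4 at 3.29 ± 0.24. The nitrogen list median was 0.61 (adjusted p = 0.00046, or 0.28 with estimated correlation). For trehalose and glycogen 7 were called higher, 0 lower and 12 not (8 and 0 over the list alone). The storage carbohydrate median was 0.60 (adjusted p = 0.0044, or 0.61 with estimated correlation).

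In the chemostat limma called 1613 probe sets between the strains, 736 higher in YSBN2 and 877 lower, with 191 and 302 at least 2-fold. The larger side turned with a common array median (51.9% of the calls higher) and quantile normalization (52.6%), against 45.6% as deposited. The groups were fully separated in 2889 probe sets (50.5%, against 10% by chance). Runs without 1 array called from 1056 to 1389, the fewest without the second CEN.PK 113-7D array (450 higher), with 436 higher without the second YSBN2 array and 571 and 564 lower without the third CEN.PK 113-7D or the first YSBN2 array. Across probe sets the strain effects in the 2 cultures correlated at r = 0.52 (rho = 0.46). Of 746 probe sets called in both cultures 672 (90.1%) had the same direction, 355 higher and 317 lower, against 136 and 92 for independent lists of these sizes.

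Which genes responded to the chemostat differently in the 2 strains was tested as the difference of the culture effects, YSBN2 minus CEN.PK 113-7D. PHO84 went from 2.39 ± 0.48 to 6.28 ± 0.59 in CEN.PK 113-7D and from 14.62 ± 0.26 to 2.35 ± 0.47 in YSBN2 (n = 3 arrays each), a difference of -16.15 ± 0.50 between the effects (SE, adjusted p = 8.1e-08). SPL2 (-9.64 ± 0.77), GPH1 (-7.41 ± 0.21), the urea transporter gene DUR3 (-7.38 ± 0.63), the proline permease gene PUT4 (-7.25 ± 0.87) and the malate synthase gene MLS1 (-7.21 ± 0.89) also had the lower effect in YSBN2. For GPH1, DUR3 and PUT4 the YSBN2 level was already high in batch, at 11.27, 9.55 and 11.85, against 2.95, 3.31 and 5.09 in CEN.PK 113-7D. AGA2 (5.42 ± 0.57) and FUS1 of cell fusion (4.45 ± 0.65) had the higher effect in YSBN2.

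Among the largest differences PAU3 (-8.19 ± 0.42), ANS1 (-7.56 ± 0.40) and YJR115W (-7.47 ± 1.01) were near the floor in YSBN2 and IMD2 (-7.55 ± 0.26) fell further there. Upward, YER053C-A (6.41 ± 1.24), YIL046W-A (6.10 ± 0.59), COS12 (5.04 ± 0.43), the pheromone desensitization gene SST2 (4.35 ± 0.72) and SEO1 (4.14 ± 0.71) were called in the deposited values. MAL33 (6.23 ± 1.47, adjusted p = 0.02) lost its call without the second CEN.PK 113-7D chemostat array (adjusted p = 0.051). The calls of MFA2 (4.78 ± 1.24, adjusted p = 0.029) and FAR1 (3.75 ± 0.99, adjusted p = 0.032) were lost in most runs without 1 array, at adjusted p from 0.052 to 0.072 and from 0.059 to 0.069.

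**Figure D4:**
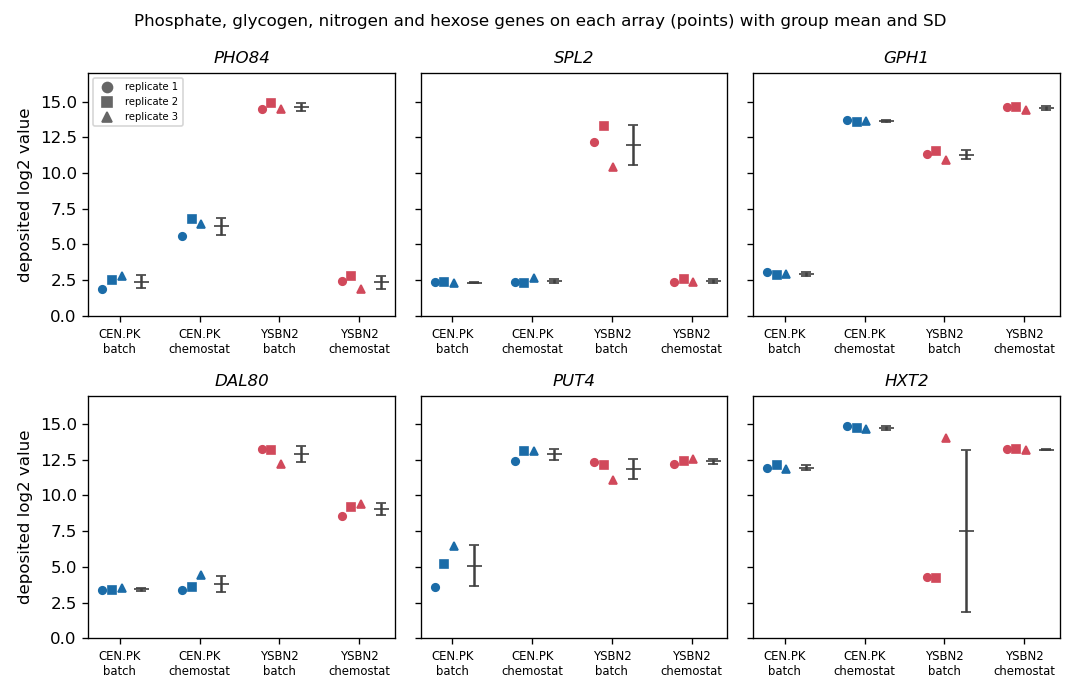
Log2 signal of 6 genes of phosphate, storage, nitrogen and glucose use in each array (points, marker by replicate) of the 4 groups, with the group mean and SD (bars). PHO84 lay at 14.62 in YSBN2 batch and under 7 in the other groups. HXT2 read 4.26, 4.21 and 14.04 in the YSBN2 batch arrays.

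The stress, storage and vacuolar lists rose less in YSBN2, and the phosphate list (median 0.19 in CEN.PK 113-7D, not called, and -0.64 in YSBN2) and the nitrogen list (0.40 and -0.40, called in neither) had the lower effect there. For heat shock and general stress 0 were called higher, 14 lower and 8 not (0 and 17 over the list alone). The stress median was -1.18 (adjusted p = 3.5e-11, or 0.21 with estimated correlation). Among trehalose and glycogen genes 1 were called higher, 13 lower and 5 not (same over the list alone). The storage carbohydrate median was -1.66 (adjusted p = 2.8e-07, or 0.31 with estimated correlation). Of the phosphate regulon 0 were called higher, 11 lower and 6 not (0 and 12 over the list alone). The phosphate median was -1.22 (adjusted p = 7.1e-07, or 0.21 with estimated correlation), with 6 lower after quantile normalization. In the vacuolar list 0 were called higher, 12 lower and 14 not (1 and 15 over the list alone). The vacuolar median was -1.0 (adjusted p = 1.4e-06, or 0.28 with estimated correlation). For nitrogen source use 2 were called higher, 13 lower and 12 not (4 and 16 over the list alone). The nitrogen list median was -1.0 (adjusted p = 4e-04, or 0.31 with estimated correlation). In the TCA cycle 0 were called higher, 8 lower and 8 not (0 and 10 over the list alone). The TCA cycle median was -0.46 (adjusted p = 4e-04, or 0.41 with estimated correlation), with 3 lower when arrays had a common median. Of the proteasome genes 0 were called higher, 10 lower and 24 not (0 and 12 over the list alone). The proteasome median was -0.33 (adjusted p = 4e-04, or 0.41 with estimated correlation), with 1 lower when arrays had a common median. For amino acid biosynthesis 2 were called higher, 15 lower and 41 not (2 and 18 over the list alone). The amino acid median was -0.25 (adjusted p = 0.0021, or 0.43 with estimated correlation), with 9 lower when arrays had a common median.

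Fatty acid oxidation and peroxisome genes also rose less: 0 were called higher, 5 lower and 15 not (0 and 8 over the list alone). The fatty acid median was -0.68 (adjusted p = 0.013, or 0.41 with estimated correlation), with a median of -0.45 without the first CEN.PK 113-7D batch array (adjusted p = 0.024) and the call lost without the third YSBN2 batch array (adjusted p = 0.05) or the 25% dimmest probe sets (adjusted p = 0.14). For ethanol and acetate use, the glyoxylate cycle and gluconeogenesis 1 were called higher, 5 lower and 12 not (1 and 6 over the list alone). The gluconeogenesis median was -0.63 (adjusted p = 0.026, or 0.41 with estimated correlation). Without the second YSBN2 batch array that median was -0.97 (adjusted p = 0.018), and the call was lost without the first CEN.PK 113-7D chemostat array (adjusted p = 0.053), the third YSBN2 batch array (adjusted p = 0.096), the second YSBN2 chemostat array (adjusted p = 0.066), the 25% dimmest probe sets (adjusted p = 0.24) or with values under 6 raised to 6 (adjusted p = 0.071).

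The a-specific list had the higher effect in YSBN2: 5 were called higher, 0 lower and 2 not (6 and 0 over the list alone). The a-specific median was 3.39 (adjusted p = 6.5e-06, or 0.21 with estimated correlation). Haploid-specific genes also had it: 5 were called higher, 1 lower and 9 not (7 and 1 over the list alone). The haploid-specific median was 0.77 (adjusted p = 0.0015, or 0.32 with estimated correlation). The haploid-specific call was lost without the 25% dimmest probe sets (adjusted p = 0.066). For the respiratory chain and ATP synthase 10 were called higher, 1 lower and 22 not (11 and 1 over the list alone). The respiratory median was 0.30 (adjusted p = 6.6e-06, or 0.21 with estimated correlation), with 16 higher without the third YSBN2 batch array. Of the cytosolic ribosomal protein genes 26 were called higher, 0 lower and 102 not (29 and 0 over the list alone). The ribosomal protein median was 0.20 (adjusted p = 1.2e-17, or 0.21 with estimated correlation), and with cyclic loess 12 were higher. Among translation factors 2 were called higher, 1 lower and 34 not (1 and 1 over the list alone). The translation factor median was 0.07 (adjusted p = 0.026, or 0.52 with estimated correlation). That call was lost without the first YSBN2 batch array (median 0.02, adjusted p = 0.11), the second (median 0.00, adjusted p = 0.073) or the first YSBN2 chemostat array (adjusted p = 0.075), and with cyclic loess (adjusted p = 0.094). Without the third YSBN2 batch array its median was 0.20 (adjusted p = 0.0026), without the first CEN.PK 113-7D batch array 0.11 (adjusted p = 0.019) and without the third YSBN2 chemostat array 0.12 (adjusted p = 0.034). Ribosome biogenesis was not called (median 0.10, adjusted p = 0.085), but was without the third YSBN2 batch array (median 0.43, adjusted p = 2.1e-07), the third CEN.PK 113-7D batch array (adjusted p = 0.042) or the third YSBN2 chemostat array (adjusted p = 0.036). Glycolysis (1 higher, 4 lower, median -0.14, adjusted p = 0.057) was not called either, but was in 9 of 19 alternatives: with cyclic loess (adjusted p = 0.0048), with fry (adjusted p = 0.0034) and without 1 array (adjusted p from 0.019 to 0.047), namely any CEN.PK 113-7D batch array, the third CEN.PK 113-7D chemostat array, the first YSBN2 batch array, or the first or the third YSBN2 chemostat array.

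The difference of the culture effects was called in 882 probe sets, 248 higher in YSBN2 and 634 lower, with 78 and 390 at least 2-fold. Without the third YSBN2 batch array 1482 were called, 586 higher and 896 lower, while 131 were higher without the second CEN.PK 113-7D chemostat array, 159 without the second YSBN2 batch array and 152 without the second YSBN2 chemostat array. A common array median shifted the median of all differences by 0.15 and quantile normalization by 0.13, with 45.9% and 50.7% of the calls higher against 28.1% as deposited.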

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

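The tests of CEN.PK 113-7D RNA, of one share of a-type cells and of glucose running out were chosen only after the result was seen, and the other tests before.

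A difference between groups singled out the following results: the chemostat effect differed between the strains, by limma's test of the difference itself. This was so for 882 probe sets. Of 100 assignments of strain within each culture, 1, the real assignment, called 882 or more. The highest of the others called 719 (median 0). The others mixed strains within groups, which widens the spread, so random assignment is not excluded as the source of the count. The arrangement with the strains swapped throughout 1 culture was not drawn and called 2369, which tests the sum of the strain effects. For the comparisons of 2 groups, the 10 splits of 6 arrays are too few for a share under 0.05. The real split called 3458 and 2511 for culture in CEN.PK 113-7D and YSBN2 and 955 and 1936 for strain in batch and chemostat. The other splits called 0.

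Of the named genes, the difference of the chemostat effect (YSBN2 minus CEN.PK 113-7D, log2) was negative for PHO84 (-16.15), SPL2 (-9.64), PAU3 (-8.19), ANS1 (-7.56), IMD2 (-7.55), YJR115W (-7.47), GPH1 (-7.41), DUR3 (-7.38), PUT4 (-7.25), MLS1 (-7.21), ARO10 (-6.54), YLR031W (-6.36), RSB1 (-6.06), QDR2 (-6.03), GNP1 (-5.43), HXK1 (-5.25), AMS1 (-5.05), YAR066W (-4.96), OPT2 (-4.73), DAL80 (-4.20), DIP5 (-4.13), GLK1 (-3.00), GRE1 (-2.80), MIG3 (-2.50), CAT8 (-2.32), FDH1 (-2.23), AIF1 (-1.85), DAL4 (-1.58), ASP3-1 (-1.18), CLB1 (-1.13), HXT5 (-0.75), MRP8 (-0.64), SFC1 (-0.64) and CUP1-1 (-0.35). It was positive for YER053C-A (6.41), MAL33 (6.23), YIL046W-A (6.10), AGA2 (5.42), COS12 (5.04), MFA2 (4.78), FUS1 (4.45), SST2 (4.35), SEO1 (4.14), FAR1 (3.75), STE2 (3.51), YDL241W (3.46), STE6 (3.39), YJL047C-A (3.30), PAU18 (3.04), SNO3 (1.54), COS8 (0.85), HO (0.77) and ADY2 (0.66).

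In the first pattern a-specific genes (median 2.65) and some haploid-specific genes were higher in YSBN2 chemostat than batch. Of 5 alpha-specific genes 3 were called higher (median 1.93, list not called). RNA of CEN.PK 113-7D in these arrays is argued against, since 4 genes bright in CEN.PK 113-7D and near the floor in YSBN2 batch had a median change of 0.10, with HO and FUS3 still at 2.20 and 1.95, though AGA2 of the same 4 rose by 5.71. The test first required genes outside the mating lists (0 found) and was widened and its rule set after the AGA2 value was seen. A general rise of dim probe sets is open. In 104 the median change was 0.03, but floor sets are uninformative, and 5.8% rose by 2 or more. One share of a-type cells with the transcript levels of CEN.PK 113-7D was tested too. The distances of the 7 a-specific genes below their CEN.PK 113-7D chemostat level, which one share would keep within 2, spanned 5.46, and 2.23 without BAR1. Of 15 a-specific and haploid-specific genes at 10 or above in the CEN.PK 113-7D chemostat, FUS3 (-8.23), BAR1 (-7.31), STE18 (-5.69) and HO (-9.41, disrupted in YSBN2 per the labels) lay more than 2 below the median a-specific distance of -3.50, a count added after the values were seen. A share of a-type cells with other transcript levels, and a change of mating-gene transcription with the culture in YSBN2, stay open and untested.

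The second pattern is that some probe sets were near the floor in one strain in both cultures and bright in the other. Sequence absent from or different in CEN.PK 113-7D, on an array designed from S288C, is a candidate explanation: 12 probe sets were near the floor in CEN.PK 113-7D and 3 in YSBN2 (two-sided exact binomial p = 0.035). These are AIF1, HAL5, EHD3, DAL80, FCY22, COS8, ARN2, AYT1, IME4, PHO5 and ENA5 with 2 probe sets, against HO, FUS3 and BAR1. That met the criterion as first written. By gene, a requirement added after the values were seen, it was 11 against 3 (exact binomial p = 0.057), so it is left open. A difference in transcription, as by mating type for HO, FUS3 and BAR1, stays open. Sequence missing in CEN.PK 113-7D cannot explain these 3, which were bright there. For the other genes the 2 explanations are not separated.

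The third pattern is that phosphate, storage carbohydrate, nitrogen and vacuolar genes were higher in YSBN2 batch than in CEN.PK 113-7D batch. PHO5 and DAL80 also belong to the second pattern. Glucose running out earlier in the YSBN2 batch cultures stays open. Against it, the median strain difference of the gluconeogenesis list was 0.058 of its culture effect in CEN.PK 113-7D and that of the fatty acid list 0.08, with 0.52 for trehalose and glycogen and 0.54 for the vacuolar list. However, without genes under 6 in both batch groups (added after the values were seen), the first 2 ratios were 0.28 and 0.17, where under 0.2 was set against it and 0.5 for it. No gene of those lists was called lower in YSBN2, 5 and 7 were called higher, with MLS1 at 3.59 and CAT8 at 3.03, and the glucose-repressed HXK1 (5.54) and GLK1 (3.06) were higher. One deviating array is argued against, since the highest adjusted p of the 4 lists over the 24 results without 1 batch array was 3e-06. A general rise of dim probe sets is open. Over 716 outside these lists the median was 0.01, but floor sets are uninformative, and 21.5% rose by 1 or more. A strain difference in batch culture may remain as a hypothesis, found on these data alone.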

How the results depend on the processing

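Settings that raise values under 6 to 6, block the replicate number within 6 arrays, or apply a common array median and quantile normalization to list counts were chosen after seeing the data, and the others before. In no setting did a test reverse its direction while called, but the median of the thiamine list for strain in batch turned from -0.08 to 0.04 without the first CEN.PK 113-7D array and to 0.02 without the second YSBN2 array while its call stayed. Among the counts of calls 243 values stayed within 1.5 times the reported one and 69 did not, and the correlations (rho included) ran from 0.8 to 0.84 between the culture effects and from 0.46 to 0.52 between the strain effects. Of the named genes' values 4286 kept their direction and side of the threshold and 85 lost the call. For lists 2141 kept both, 118 lost the call (83 of them with an estimated correlation) and 64 gained it (40 of them with fry). For each shift below the cause was not tested, except where fewer probe sets, fewer arrays or a stricter threshold leave fewer calls by construction. Planned runs on all lines of the value table were not run separately, because it holds no control or other-organism probe sets.

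Without the 50% dimmest probe sets, 1790 were called for the CEN.PK 113-7D culture effect (892 higher), 1665 for that of YSBN2 (803 higher), 1024 for strain in batch (607 higher), 1053 for strain in the chemostat (471 higher, 582 lower) and 532 for the difference of effects (358 lower). With treat at 1.5-fold, in the same order, 1317 (990 higher, 327 lower), 1236 (786 and 450), 413 (314 and 99), 265 (95 and 170) and 240 (28 and 212) were called. At an adjusted p under 0.01 the last 3 comparisons gave 947 (644 and 303), 860 (358 and 502) and 407 (76 and 331). With array weights, whose estimation stopped short of its convergence tolerance, these gave 3080 (1678 and 1402), 2547 (1153 and 1394) and 1974 (741 and 1233). A common array median gave 2143 lower for the CEN.PK 113-7D culture effect and 409 higher for the difference of effects, and quantile normalization 2160 and 537. In a fit of the 6 batch arrays 955 were called for strain (624 higher, 331 lower).

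With the replicate number as a block in the 12-array fit, the counts were 3311, 3128, 1787, 1757 and 963, within 1.5 times the reported ones, and the block changed no list call but that of the proteasome in CEN.PK 113-7D. With the block in fits of 6 arrays, 3736 were called for culture in CEN.PK 113-7D (2187 higher, 1549 lower), taken as paired, 1927 for culture in YSBN2 (1160 and 767), 507 for strain in batch (353 and 154) and 1815 for strain in the chemostat (780 and 1035). In the last 3 no pairing was taken: of the 6 arrays 2, 4 and 2 correlated best with their own number. Calls lost with that block, besides those named with their results, were of ATG18 for culture in YSBN2 (adjusted p = 0.066), of CUP1-1 and MLS1 for strain in batch (adjusted p = 0.091 and 0.1) and of GND2 and RPE1 for strain in the chemostat (adjusted p = 0.085 and 0.061).

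Runs without 1 array ranged from 399 to 1115 lower for strain in batch. For strain in the chemostat they ranged from 1056 to 1389 in all, 436 to 627 higher and 564 to 820 lower, and for the difference of effects from 593 to 1482 in all and 131 to 586 higher.

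Lists called higher with fry numbered 21 for culture in CEN.PK 113-7D, 19 for culture in YSBN2 and 13 for strain in batch, and lists called lower 16 for strain in the chemostat and 18 for the difference of effects. With an estimated correlation 0 lists were called in either direction in each comparison except strain in the chemostat (1 higher, 1 lower). With cyclic loess 5 lists were lower for culture in YSBN2, and without the 25% dimmest probe sets 3 were higher for the difference of effects. Medians of called lists that moved over 1.5 times and stayed called were, without the 25% dimmest probe sets, gluconeogenesis (5.19) and stress (1.83) for culture in CEN.PK 113-7D, stress (0.75) and phosphate (-1.23) for culture in YSBN2, and nitrogen for strain in the chemostat (0.24) and the difference of effects (-0.49). With values under 6 raised to 6 they were sugar use for culture in YSBN2 (1.66) and nitrogen for strain in the chemostat (0.29), and with cyclic loess ribosomal proteins for culture in CEN.PK 113-7D (-0.18) and the difference of effects (0.13) and thiamine for strain in batch (-0.13). Other lists not called gained a call, besides with fry: pentose phosphate without the 25% dimmest probe sets for culture in CEN.PK 113-7D (adjusted p = 0.039) and strain in batch (0.0087, or 0.034 without the first CEN.PK 113-7D array), ergosterol with cyclic loess for culture in YSBN2 (0.041), thiamine for strain in the chemostat with cyclic loess (0.048), values under 6 raised to 6 (0.045) or without the third YSBN2 array (0.043), and for the difference of effects iron without the second YSBN2 chemostat array (0.044) and subtelomeric genes without the third CEN.PK 113-7D batch array (0.033).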

Other observations

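Several gene groups were not called as lists but held large changes. Of 17 hexose transporter and sensor genes 5 rose and 2 fell in the CEN.PK 113-7D chemostat (adjusted p = 0.73 for the list), with the glucose sensor gene SNF3 at 4.89 ± 0.47 and the low-affinity transporter gene HXT3 at -3.66 ± 0.35, and 4 rose and 2 fell in YSBN2 (adjusted p = 0.96), with HXT3 at -4.83 ± 0.35. In the pentose phosphate pathway the minor isoform genes TKL2 (10.37 ± 0.20 and 9.74 ± 0.20), GND2 (9.44 ± 0.19 and 8.71 ± 0.19) and NQM1 (9.18 ± 0.73 and 9.40 ± 0.73) rose in both strains, while ZWF1 of the first step fell (-1.10 ± 0.22 and -1.07 ± 0.22), and the list was not called in either (adjusted p = 0.86 and 0.38). Of the iron regulon 11 rose and 3 fell in CEN.PK 113-7D and 7 and 7 in YSBN2 (adjusted p = 0.39 and 0.64), with the reductase gene FRE4 at 6.87 ± 0.54 and 6.72 ± 0.54 and the ferroxidase gene FET3 at -1.50 ± 0.11 and -1.53 ± 0.11. Meiosis genes included RIM4 (7.48 ± 0.50 and 5.58 ± 0.50) and SPS4 (-3.80 ± 0.29 and -4.10 ± 0.29), with 8 higher and 1 lower of 22 in each strain (adjusted p = 0.17 and 0.12). The seripauperin gene PAU2, whose family is near-identical, rose by 11.35 ± 0.19 and 10.48 ± 0.19, in a list of anaerobic genes that was not called (adjusted p = 0.73 and 0.64). Nor were mitochondrial ribosomal proteins (adjusted p = 0.45 and 0.6), nitrogen source use (adjusted p = 0.22 and 0.1) or cell cycle genes (adjusted p = 0.26 and 0.61) called between cultures.

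Between the strains, HMX1 of heme degradation was lower in YSBN2 (-5.55 ± 0.42 in batch, -3.76 ± 0.42 in the chemostat), as was the mannoprotein gene TIR3 (-5.68 ± 0.84 and -4.37 ± 0.84), and SPS4 was higher (4.63 ± 0.29 and 4.33 ± 0.29). Of the 3 measured loci known as background to be missing or of lower copy in CEN.PK 113-7D, ENA5 was higher in YSBN2 in both cultures, ASP3-1 by 1.61 ± 0.08 and 0.44 ± 0.08, and CUP1-1 by 0.34 ± 0.06 in batch with a difference of -0.02 ± 0.06 in the chemostat that was not called. Among subtelomeric genes, which have near-identical copies, AAD3 was higher (4.07 ± 0.49, or 0.57 and not called with values under 6 raised to 6, and 5.48 ± 0.49) and COS7 lower (-2.87 ± 0.22 and -2.63 ± 0.22), and the list was not called (adjusted p = 0.76 and 0.86). Of 5 alpha-specific genes MF(ALPHA)1, encoding alpha factor, was higher in YSBN2 than in CEN.PK 113-7D in the chemostat (4.80 ± 0.83, adjusted p = 0.0028), at 8.90 against 4.10, and the list was not called (adjusted p = 0.25). The flocculation list was not called in batch or in the chemostat (adjusted p = 0.62 and 0.86).

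The third YSBN2 batch array differed from the other two by 0.35 and 0.324 (median absolute log2 difference), against 0.119 between those. Its weight in limma's array weights was 0.11. Besides HXT2, it read ECM13 at 13.42 against 3.05 and 3.02 and MET32 of sulfur metabolism at 8.55 against 11.39 and 11.15, genes chosen after their values were seen. The first and second YSBN2 batch arrays shared 79 values equal to all 3 decimals deposited, against 1 to 19 in the other pairs of replicates.

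In some lists that were not called, mean, median and test direction included opposite signs. In the CEN.PK 113-7D culture comparison these were mitochondrial ribosomal proteins, glycolysis, anaerobic genes and the pentose phosphate pathway, and in YSBN2 mitochondrial ribosomal proteins, hexose transporters, cell cycle, iron and flocculation. Between strains in batch they were the pentose phosphate pathway, amino acid biosynthesis, hexose transporters, sugar use, anaerobic and subtelomeric genes, and in the chemostat gluconeogenesis, iron, subtelomeric and anaerobic genes. For the difference of effects they were mitochondrial ribosomal, cell cycle, anaerobic, sulfur amino acid, alpha-specific, pentose phosphate and meiosis genes.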
